A study of Mus musculus with 12 samples.

How the data were processed

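CUT&RUN libraries of sorted mouse dendritic cells were made with commercial kits, per the labels' protocols, in 6 groups of 2 samples. The submitters' processing notes name Trim Galore 0.6.10, cutadapt 4.5, Bowtie2 2.5.2, SAMtools 1.18, bedtools 2.31.0, MACS3 3.0.2 and the mm10 genome, without their roles, order or settings. The effect of adapter trimming, duplicate removal, blacklists and the handling of multi-mapping reads on the lists is therefore not known.

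The authors deposited 3 peak lists that were used here. The anti-HA list is a BED file with positions and a score that the authors left at 0 in every line, so its intervals could be ranked only by width. Each H3R17me2a list is a narrowPeak file with the authors' integer score, a fold enrichment (a ratio of fragments to background), −log10 p and −log10 q values, and a summit position, all as deposited. The lowest −log10 q was 1.30 in the control list and 1.31 in the Carm1-KO list, close to a q of 0.05. The anti-HA list is attached to the replicate 1 record of its group. The H3R17me2a lists are attached to the IgG replicate 1 records of control and Carm1-KO cells, and the peak names inside them give H3R17me2 and the genotype. They were taken as the H3R17me2a lists of those genotypes. Whether replicates were pooled before peak calling is not given in the sources used here, so no list per replicate was compared and no p-value is given for a difference between conditions.

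Comparisons used chromosomes 1 to 19, X and Y. No list held overlapping intervals. Peaks counted as shared when they overlapped by 1 bp or more. Shares carry 95% Wilson intervals, which cover counting error only and treat neighbouring peaks as independent. Each observed overlap was set beside 1000 random placements of the intervals on the same chromosomes, which do not avoid gaps or unmappable DNA, and so overstate the excess over chance. Location used the summit for H3R17me2a peaks and the midpoint for anti-HA intervals, with 100 random placements.

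Genes came from a RefSeq gene table of the GRCm38.p6 assembly, the same build as mm10, with 21774 protein-coding genes after leaving out 113 on other sequences. The table gives gene starts and ends, and neither strand nor exons. The design fixed before the data were examined called for promoters, exons and introns. Instead a peak was assigned to a gene end (within 1000 bp of either end), the gene body, within 10 kb of a gene, or elsewhere. Random gene lists were matched on length decile only. The planned use of the most upstream start alone, exons of Carm1 and motif content need strand, exons or sequence and were not analysed here.

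The 16 gene lists were fixed before the data were examined. Of their members, 302 were in the table, and Mx1 and Mx2 were not. Each list was set beside 10000 random lists of the same size, and its percentile describes these peak lists without a test. For the share of control-only members, random genes with a control peak were matched in 10 bins of control fold, a choice made after seeing the data. Named genes followed a rule fixed in advance: Carm1; list members with an anti-HA interval at a gene end; the 10 genes with the highest control fold and no Carm1-KO peak within 10 kb; the same in the other direction; the 10 genes with the widest anti-HA interval at a gene end; and up to 4 members per list and class by fold.

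Read depth was not given. Fragments at the summit and local background were solved for each H3R17me2a peak from the deposited fold and −log10 p, under a Poisson model with a pseudocount of 1 as MACS uses. The lowest background was read as genome-wide coverage, which assumes the caller's default background and the same genome size for both lists, since its settings are not given in the sources used here. Whole fragment numbers were taken to show that the antibody libraries were not scaled, and the shortest interval of each list stood for the fragment length. A whole number of fragments had to return the deposited −log10 p within a relative tolerance of 0.0001. Tested on 2000 simulated peaks, the method recovered 100% of whole pileups and solved 0.95% of scaled ones. The overlap code recovered 100% of 300 planted overlaps and called 0% of 700 intervals without one. A planted gene list with an excess lay at percentile 99.995 of random lists, and 3.5% of 200 random lists exceeded the percentile of 95. The pooled ratio over bins of −log10 q used in the closing section returned 1.50 for a planted ratio of 1.5. Its interval covered 1 in 95 of 100 simulations in which the outcome followed these same bins alone.

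Alternatives fixed in advance were −log10 q of 5 or more, fold of 5 or more, a control list shortened to the Carm1-KO length, overlap of at least 50% of the shorter interval, a gap of up to 1000 bp, every sequence name, windows of 250 and 2500 bp around gene ends, and any peak within 10 kb of a gene. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.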

Results

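CUT&RUN maps where a protein or a histone mark sits on DNA: an antibody guides a nuclease to its target in permeabilised cells, and the DNA it releases is sequenced. The samples were sorted mouse dendritic cells, 500000 per sample. They concern CARM1 (also called PRMT4), an arginine methyltransferase that acts as a transcriptional coactivator, and H3R17me2a, the asymmetric dimethylation of arginine 17 of histone H3 that CARM1 can place. Conventional type 1 dendritic cells (cDC1) are specialised in presenting captured antigen to cytotoxic T cells. The labels give 12 samples in 6 groups of 2: type 1 dendritic cells (DC1) expressing HA-tagged Carm1 with anti-HA or IgG, control cDC1 with anti-H3R17me2a or IgG, and Carm1-KO cDC1 with anti-H3R17me2a or IgG. IgG, a non-specific antibody, measures the background. The values come from 3 peak lists, 1 for anti-HA in the Carm1-HA cells and 1 for H3R17me2a in each cDC1 genotype. With 1 list per condition, none of the differences between conditions has a replicate check. Intervals in brackets are 95% Wilson intervals that cover counting error only.

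The control H3R17me2a list held 59031 peaks over 28.9 Mb, with a median width of 370 bp. The Carm1-KO list held 25826 peaks over 9.09 Mb, with a median width of 302 bp. The anti-HA list held 6101 intervals on chromosomes 1 to 19, X and Y, over 1.85 Mb, with a median width of 284 bp. Fold enrichment and −log10 q are the authors' peak caller's values, and here they describe, rank and filter the peaks of each list by itself. A fold of 1 list is not on a common scale with a fold of the other, so folds are not compared between lists. The number of fragments at each H3R17me2a summit was solved from the caller's fold and −log10 p, and came out whole for 100% of the peaks in both lists. The median was 25 fragments in the control list and 28 in the Carm1-KO list. The lowest solved background was 3.10 fragments in the control list and 4.19 in the Carm1-KO list. The shortest intervals, which the caller by default bounds at the fragment length, were 184 and 187 bp, and per bp of these the Carm1-KO background was 1.329 times that of the control list. Whole fragment numbers show that the antibody libraries were not scaled, and reading the lowest background as their genome-wide coverage further assumes the caller's default background and 1 genome size for both lists. The depth behind the anti-HA list is unknown.

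At Carm1 itself (chromosome 9, 21546894 to 21589467 in mm10), both H3R17me2a lists had a peak at the lower-coordinate end of the gene. The control peak ran from 21545951 to 21546627 with a fold of 4.03. The Carm1-KO peak lay inside it, from 21546325 to 21546512, with a fold of 2.57. A second pair lay beyond the other end of the gene, at 21592101 to 21593336 in the control list and 21592534 to 21592760 in the Carm1-KO list. No list had a peak in the rest of the gene body, and no anti-HA interval lay within 10 kb of the gene. A peak list does not show whether an exon is deleted, so these positions do not check the genotype labels.

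The comparison of control with Carm1-KO cDC1 asks which H3R17me2a peaks are called with and without CARM1. Of the 59031 control peaks, 43024 (72.9%, [72.5 to 73.2]) had no overlapping Carm1-KO peak and 16007 did. Of the 25826 Carm1-KO peaks, 9025 (34.9%, [34.4 to 35.5]) had no overlapping control peak. The shared part was far above chance: 65.1% of Carm1-KO peaks overlapped a control peak, against a mean of 2.00% when they were placed at random on the same chromosomes. Overlap rose with strength. In the weakest quintile of control peaks by −log10 q, 9.73% had a Carm1-KO peak, and in the strongest quintile 60.1% [59.2 to 60.9] did. In the Carm1-KO list the share with a control peak rose from 46.2% to 92.0% [91.2 to 92.7]. When the control list was shortened to its 25826 strongest peaks, 55.6% of them had no Carm1-KO peak and 52.3% of the Carm1-KO peaks had no control peak. Overlap was close to 1 to 1, with 16007 control and 16801 Carm1-KO peaks in the shared part, so the longer list has the larger unmatched share by construction, and the remaining difference at equal length arises where several Carm1-KO peaks fall in 1 control peak. At a fold of 5 or more, applied to each list on its own scale and reached by 5075 control and 493 Carm1-KO peaks, the shares were 95.7% and 55.8%.

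**Figure D1:**
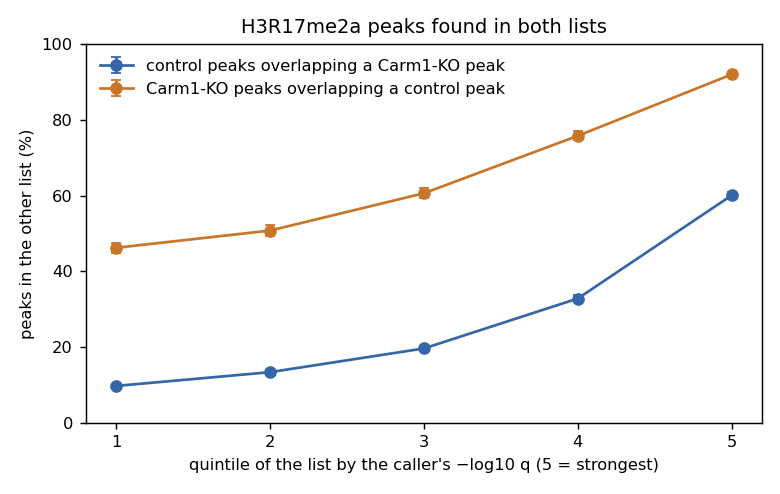
Share of H3R17me2a peaks that overlap a peak of the other list (y axis, %), by quintile of each list ranked on the caller's −log10 q (x axis, 5 is the strongest), with 95% Wilson intervals. The share rose from 9.73% to 60.1% for control peaks and from 46.2% to 92.0% for Carm1-KO peaks.

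H3R17me2a peaks gathered at the ends of genes. The gene table used here gives no strand, so "gene end" means within 1000 bp of either end of a protein-coding gene, and a transcription start cannot be told from an end. Summits at a gene end made up 22.7% [22.3 to 23.0] of control peaks and 25.4% [24.8 to 25.9] of Carm1-KO peaks, against 3.18% and 3.15% at random places. The peaks of both lists lay there most often: 33.8% [33.1 to 34.6] of shared control peaks, 18.5% [18.1 to 18.9] of control-only peaks and 8.82% [8.25 to 9.42] of Carm1-KO-only peaks. Within each quintile of −log10 q, control peaks at gene ends had a Carm1-KO peak more often than the others, from 15.2% against 8.92% in the weakest quintile to 62.8% against 58.0% in the strongest. The peaks at gene ends were also wider, with medians of 810 and 650 bp in the strongest quintile.

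Of 21774 protein-coding genes, 11607 had a control peak at a gene end and 6759 a Carm1-KO peak. Both lists had one at 6365 genes, the control list alone at 5242, the Carm1-KO list alone at 394, and neither at 9773. A gene counted as having both when each list had a peak at either of its ends, and these peaks need not overlap. The fold given for a gene is that of its highest gene-end peak in the list named. With the control list shortened to the length of the Carm1-KO list, 3504 genes had a control peak alone and 1217 a Carm1-KO peak alone.

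In the 16 fixed gene lists, 101 genes had a gene-end peak in the control list alone, and 59 of these (58.4%) had a Carm1-KO peak elsewhere within 10 kb of the gene, while 42 had none. Among all 5242 protein-coding genes with a control peak alone, 55.2% had one. The 7 list genes with a Carm1-KO peak alone at a gene end all had a control peak within 10 kb, as did 266 of the 394 such protein-coding genes (67.5%). Most of these 7 list genes had a weak gene-end Carm1-KO peak. Its −log10 q was 1.71 (Neurod1) to 3.30 (Cebpe), apart from Lyz2 (7.99), against a median of 3.93 over the Carm1-KO list.

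In random genes matched on control fold, a comparison chosen after seeing the data, the number of members with a control peak alone lay between percentiles 24.2 and 81.2 for 13 of the 16 lists. These include cDC1 identity (12 against a mean of 9.998, percentile 79.9), class I and cross-presentation (10 against 10.04, 50.005) and class II (4 against 5.20, 24.2). The lowest were the T cell markers (0 against 1.91, 3.55) and the Toll-like receptor and NF-kB list (7 against 11.3, 3.78), and the highest the ribosomal protein genes (12 against 9.01, 90.6).

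Most genes of the fixed cDC1 identity list had an H3R17me2a peak at a gene end in the control list. Of the 25 cDC1 identity genes, 23 had a control peak at a gene end, against a mean of 14.5 in random lists of genes of similar length (percentile 99.99), and 12 had a Carm1-KO peak. Each list had a gene-end peak for 11 of them, among them Xcr1, the receptor for the chemokine XCL1 (control fold 6.51), Wdfy4, needed for cross-presentation (5.89), Clec9a, a receptor for dead cells (5.16), and Batf3, a transcription factor required for cDC1 development (5.08). The Xcr1 peak of fold 6.51 did not overlap the Carm1-KO peak there, which overlapped another control peak (fold 3.35). A gene-end peak was in the control list alone for 12, among them Itgax, which encodes CD11c (4.53), the transcription factors Nfil3 (4.49) and Bcl6 (4.19), and Gcsam (4.42). Of these 12, 11 had a Carm1-KO peak within 10 kb of the gene. The count with both was 4 at −log10 q of 5 or more and 15 within 2500 bp of a gene end, and 23 with any peak within 10 kb. Itgae, which encodes CD103, had a gene-end peak in the Carm1-KO list alone (fold 2.41), although 11 control peaks lay within 10 kb of the gene. Peaks were dense around several of these genes, with 19 control and 5 Carm1-KO peaks within 10 kb of Flt3, 18 and 8 for Wdfy4, and 9 and 1 for Xcr1. The Carm1-KO peak of Xcr1 lay at the facing end of the neighbouring gene Fyco1 as well.

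**Figure D2:**
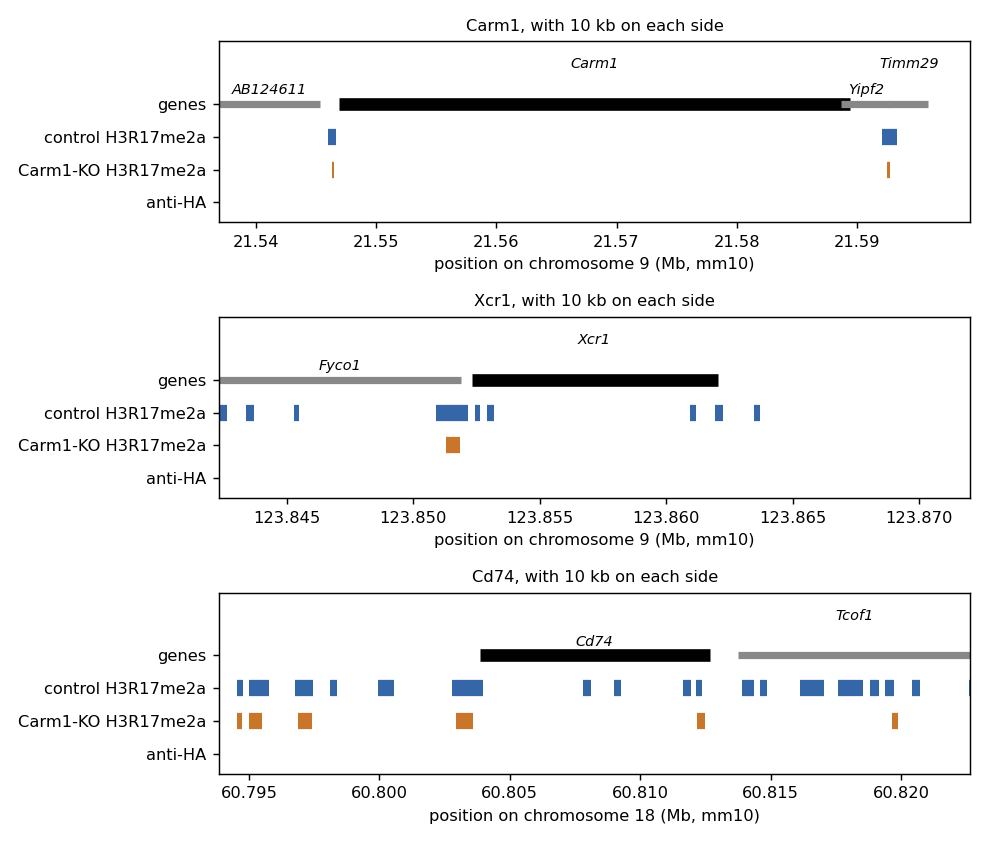
Peaks at Carm1, Xcr1 and Cd74 with 10 kb on each side (x axis, position in Mb, mm10). Black bars are the named gene, grey bars neighbouring protein-coding genes, and coloured bars the peaks of each list. Xcr1 had 9 control peaks and 1 Carm1-KO peak, Cd74 had 18 and 6, Carm1 had 2 and 2, and no anti-HA interval fell in these windows.

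Most antigen presentation genes had a control peak at a gene end. In the class I and cross-presentation list, 23 of 24 members had a control peak at a gene end (random mean 13.8) and 13 had a Carm1-KO peak. The aminopeptidase Erap1 (control fold 5.11), Rab43 (5.08), Rac2 (4.94) and the proteasome activator Psme1 (4.54) had both. A gene-end peak was in the control list alone at 10 genes, led by H2-D1, a class I heavy chain (8.50, chromosome 17, 35262355 to 35263636), the loading factor Tapbp (5.28), B2m, the class I light chain (4.68), and the immunoproteasome subunit Psmb9 (4.36). Carm1-KO peaks lay within 10 kb of 6 of these 10, with 2 at B2m and 1 at H2-D1. Neighbouring genes can share a peak. The Psmb9 control peak also lay at an end of Tap1, and 1 Carm1-KO peak (34197441 to 34197875) counted for both Tap1 and Psmb8. In the class II list, 11 of 12 members had a control peak and 7 a Carm1-KO peak. The invariant chain gene Cd74 (control fold 5.14), Rfxap (4.88), Ifi30 (4.34) and the class II transactivator Ciita (3.27) had both, while the class II chain genes H2-Ab1 (4.14), H2-Aa (3.72) and H2-Eb1 (3.43) and the loading factor H2-DMa (3.86) had a control peak alone at their gene ends. Within 10 kb there were 3 Carm1-KO peaks at H2-Ab1, 3 at H2-Eb1 and 1 at H2-DMa. Class II genes with a control peak alone fell from 4 to 2 within 2500 bp, and those with both fell from 7 to 2 at −log10 q of 5 or more. Class I genes with both numbered 7 at −log10 q of 5 or more and 20 with any peak within 10 kb. The H2 genes have close paralogs, and reads shared between them make these calls uncertain.

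Maturation and innate signalling genes were also covered. In the dendritic cell maturation and migration list, 23 of 29 members had a control peak and 16 a Carm1-KO peak. Il12b, which encodes a subunit of interleukin 12, had both (control fold 8.83, chromosome 11, 44398800 to 44400065), as did Cd40 (5.81), Icosl (5.16) and Socs1 (4.77). Cxcl16 (6.10), Marcks (5.17), Il15ra (4.29) and Cd83 (4.05) had a control peak alone at their gene ends, with 1, 1, 3 and 2 Carm1-KO peaks within 10 kb. Ccr7, the receptor that guides dendritic cells to lymph nodes, and Tnfsf4 had a gene-end peak in the Carm1-KO list alone (folds 2.39 and 2.73), with 1 and 2 control peaks within 10 kb. Maturation genes with a Carm1-KO peak alone fell from 2 to 1 within 2500 bp of a gene end. In the type I interferon list, 22 of 28 members had a control peak and 14 a Carm1-KO peak. Irf7 (control fold 6.595), Irf9 (5.40), Cmpk2 (4.84) and Bst2 (4.76) had both, Oasl1 (4.68), Isg15 (4.62), Ifit2 (4.19) and Dhx58 (4.16) a control peak alone, and Rsad2 a Carm1-KO peak alone (2.59), with 1 control peak within 10 kb. In the Toll-like receptor and NF-kB list, 26 of 27 members had a control peak and 19 had one in both lists, led by the kinases Ikbkb (control fold 7.46) and Irak4 (6.23), Nfkb1 (6.23) and Tlr4 (6.22). Map3k7 (3.48), Nfkbiz (3.33), Irak1 (3.30) and Il6 (3.22) were among the 7 with a control peak alone. Their number was 11 at −log10 q of 5 or more and 2 with the shortened control list. At −log10 q of 5 or more, a peak in both lists was left at 7 maturation, 6 interferon and 9 Toll-like receptor and NF-kB genes, and with any peak within 10 kb the counts were 27, 19 and 24.

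In the metabolic and housekeeping lists, control and Carm1-KO peaks were at 21 and 12 of 24 oxidative phosphorylation genes, 12 and 5 of 14 glycolysis genes, 20 and 10 of 21 arginine methylation and CARM1 partner genes, and 21 and 9 of 25 ribosomal protein genes. The Carm1-KO counts lay at percentiles 96.2, 57.3, 88.2 and 84.6 of random lists. Glycolysis genes with both rose from 5 to 10, and those with a control peak alone fell from 7 to 3, within 2500 bp of a gene end. With any peak within 10 kb, both lists had one at 17, 11, 14 and 14 of the genes of these 4 lists, and at −log10 q of 5 or more at 7, 4, 6 and 5. Uqcrc2 (control fold 6.27), Eno1 (4.996), Tdrd3, a reader of methylarginine (5.38), and Rpl5 (6.62) had both. Ndufa9 (6.11), Tpi1 (4.31), Gapdh (3.04), the coactivator Ncoa3 (4.09), Prmt2 (3.81) and Rplp1 (6.89) had a control peak alone. For the number of members with a control peak, the 10 lists from cDC1 identity to ribosomal proteins lay between percentiles 98.0 and 100 of random lists.

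Lists of markers of other cells were mostly within the range of random lists. A control peak was at 4 of 10 plasmacytoid dendritic cell markers (percentile 31.5), 4 of 8 B cell markers (38.6), 4 of 9 T cell markers (17.3) and 3 of 10 neutrophil and erythroid markers (13.3). Genes restricted to other organs were below it, with 4 of 24 (0.060). In the cDC2 and monocyte list it was at 9 of 12 (90.7). Within 10 kb of the gene, a control peak was at 8 of 10 plasmacytoid dendritic cell markers (88.3) and 7 of 10 neutrophil and erythroid markers (71.1), and a Carm1-KO peak at 8 of the plasmacytoid markers (97.9). Among these, Tcf4, a transcription factor of plasmacytoid dendritic cells (control fold 5.87), Klf4 (4.52), Irf4 (3.79), Cd79a (4.10), Cd3d (4.61), Klf1 (5.20) and the muscle gene Ckm (6.14) had a peak in both lists. Notch2 (3.87), Cd14 (3.41), Cd79b (3.86), S100a8 (3.30) and Apoa1 (3.53) had a control peak alone. Lyz2 (4.36), Cebpe (2.49) and Neurod1 (2.62) had a gene-end peak in the Carm1-KO list alone, with 2, 2 and 1 control peaks within 10 kb. Within 2500 bp of a gene end, the count with a Carm1-KO peak alone fell from 1 to 0 in both the cDC2 and monocyte list and the neutrophil and erythroid list. All 4 covered T cell markers, Cd3d, Cd5, Cd3e and Cd4, had peaks in both lists. At Cd4 the control and Carm1-KO peaks with the highest fold lay at opposite ends of the gene.

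**Figure D3:**
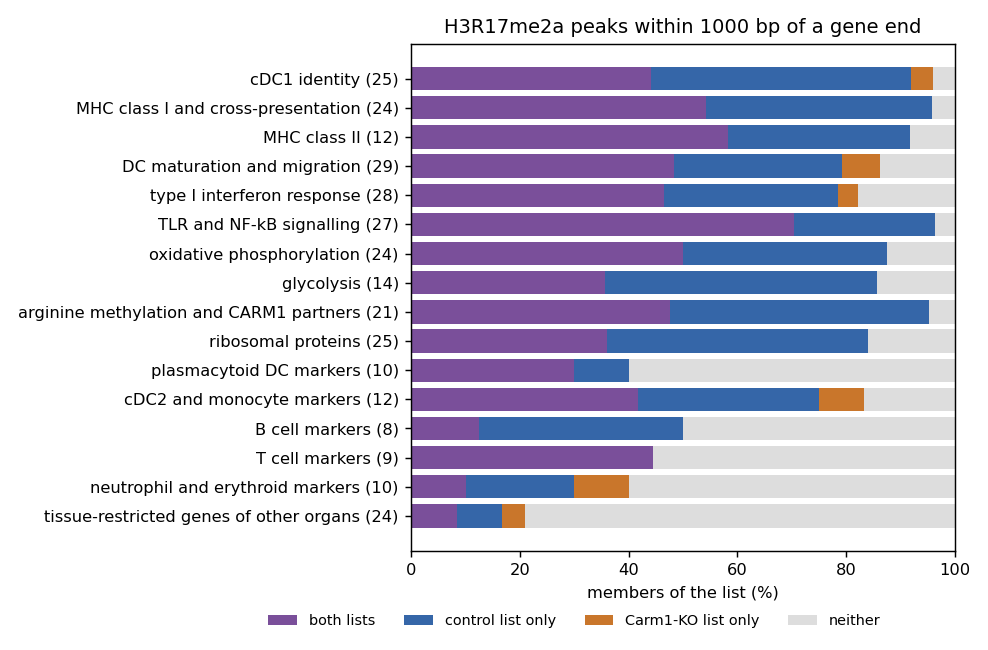
Members of each fixed gene list (x axis, % of members; number of members in brackets) with an H3R17me2a peak within 1000 bp of a gene end in both lists, the control list alone, the Carm1-KO list alone or neither. A peak in both lists was found at 11 of 25 cDC1 identity genes and 19 of 27 Toll-like receptor and NF-kB genes, and 19 of 24 genes of other organs had none.

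Ranked by fold and not by −log10 q, the 10 highest genes with a gene-end control peak and no Carm1-KO peak within 10 kb had folds of 7.59 to 10.002. These were Shcbp1 (10.002, chromosome 8, 4779188 to 4779868), the glycosyltransferase Galnt3 (8.86), the kinase Glyctk (8.73), the methyltransferase N6amt1 (8.71), the co-chaperone Dnajb6 (8.67, chromosome 5, 29734668 to 29736754), Klhl8 (8.38), the ubiquitin ligase Pja1 (7.89), the ubiquitin-conjugating enzyme Ube2e3 (7.81), the histone gene H4c17 (7.81) and Rfc5, a subunit of the replication clamp loader (7.59). Histone H4 genes are near-identical copies, so H4c17 is uncertain. In the Carm1-KO list, the 10 gene-end peaks with the highest fold and no control peak within 10 kb had folds of 3.68 to 6.36 on that list's own scale, at Zc3hc1 (6.36, chromosome 6, 30390774 to 30390992), the aldo-keto reductase Akr1e1 (4.91), Zfp975 (4.11), Obox2 (3.86), BC024063 (3.86), Gm7972 (3.81), the olfactory receptor Olfr1336 (3.75), Sh2d4a (3.70), Tmem100 (3.70) and Cited1 (3.68). Zfp975, Obox2 and Olfr1336 belong to large families of similar genes and are uncertain.

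The anti-HA list asks where tagged CARM1 lay relative to the mark. No sample used anti-HA in cells without the tag, so off-target anti-HA signal cannot be told apart from tagged CARM1. Of 6101 anti-HA intervals, 1182 (19.4%, [18.4 to 20.4]) overlapped a control H3R17me2a peak, against a mean of 1.90% and a maximum of 2.61% in 1000 random placements. A Carm1-KO peak was overlapped by 474 (7.77%, [7.12 to 8.47]), against a mean of 0.689%. These are 10.2 and 11.3 times the random means. Most anti-HA intervals, 4858 (79.6%, [78.6 to 80.6]), overlapped neither list. The overlap depended on the peaks kept: 2.75% and 0.148% of anti-HA intervals lay on control and Carm1-KO peaks with a fold of 5 or more, 3.88% on Carm1-KO peaks with −log10 q of 5 or more, and 14.6% within 1000 bp of a Carm1-KO peak. Anti-HA intervals lay at a gene end in 9.42% [8.72 to 10.2] of cases, against 3.13% at random places. The share was 31.2% [28.6 to 33.9] for those on a control peak and 4.19% [3.66 to 4.78] for the others. Control peaks themselves had their summit there in 22.7% of cases, so this contrast in part restates where control peaks lie.

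Control peaks that were also in the Carm1-KO list held an anti-HA interval more often than control-only peaks, at 3.28% [3.01 to 3.57] against 1.53% [1.42 to 1.65]. The order was the same in every tertile of −log10 q, with 1.95% against 0.945% in the weakest, 2.39% against 1.47% in the middle and 3.92% against 2.67% in the strongest. It was also the same at gene ends (4.04% against 2.11%) and elsewhere (2.89% against 1.40%). The share for control-only peaks rose to 2.55% at −log10 q of 5 or more and to 3.252% at a fold of 5 or more, where shared peaks stood at 3.82% [3.39 to 4.31] and 4.15% [2.20 to 7.69]. The last rests on 9 of 217 peaks and its difference from the control-only share is within counting error. Carm1-KO-only peaks held one in 0.554% [0.421 to 0.73] of cases. All of these shares count an overlap anywhere in the peak, which wider peaks meet more easily. Windows of 250 bp on each side of the control summit were chosen after seeing the data. With them, shared peaks stood at 2.77% [2.53 to 3.04] and control-only peaks at 1.63% [1.51 to 1.75].

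**Figure D4:**
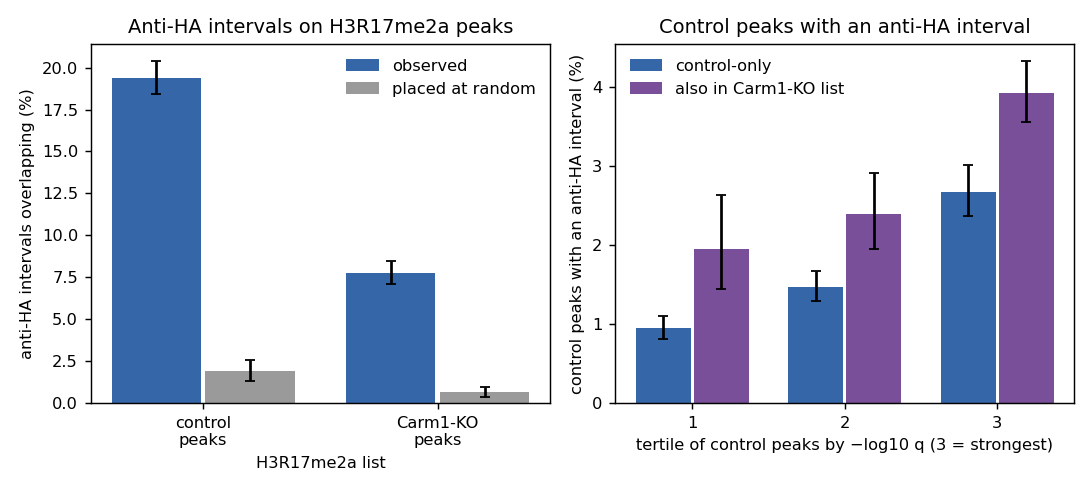
Left, share of anti-HA intervals overlapping each H3R17me2a list (y axis, %), observed with 95% Wilson intervals and placed at random with the range of 1000 placements. Right, share of control peaks overlapping an anti-HA interval anywhere in the peak (y axis, %) by tertile of −log10 q (x axis, 3 is the strongest), with 95% Wilson intervals and no adjustment for peak width. The control list was overlapped by 19.4% of anti-HA intervals, and shared peaks were above control-only peaks in each tertile.

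At the level of genes, 697 had an anti-HA interval at a gene end. The share was 5.78% [5.23 to 6.38] of genes with an H3R17me2a peak in both lists, 4.58% [4.05 to 5.18] with a control peak alone, 0.761% [0.259 to 2.21] with a Carm1-KO peak alone (3 of 394) and 0.880% [0.713 to 1.09] with neither. The widest were at Ccm2 (965 bp, chromosome 11, 6547289 to 6548253), Nudt16l1 and Anks3, which share 1 interval (783 bp), Hook2 (770 bp), Rhof and the histone methyltransferase gene Setd1b, which also share 1 (764 bp), Zfp691 (745 bp), the kinase Map2k3 (742 bp), Nsl1 (736 bp) and the phosphatase Dusp22 (724 bp). All 10 genes had a control H3R17me2a peak at a gene end, and 4 of them, Zfp691, Map2k3, Nsl1 and Dusp22, also a Carm1-KO peak. Of all 697 genes, 368 had peaks in both lists, 240 a control peak alone, 3 a Carm1-KO peak alone and 86 neither. An anti-HA interval and an H3R17me2a peak counted for the same gene need not overlap. At Hook2 the 1 control peak at a gene end (84989230 to 84989568) lay beside the anti-HA interval (84989607 to 84990376). In the fixed lists, 10 of 302 genes had an anti-HA interval at a gene end, a share close to that of all protein-coding genes (697 of 21774). These 10 were Flt3, the receptor that drives dendritic cell development, Rfxank, Tnfsf9, Il15ra, Oasl2, Oasl1, Rsad2, Traf6, Jmjd6 and Ccr9. Within 10 kb of the gene, 12 of the 25 cDC1 identity genes had an anti-HA interval, against a mean of 5.04 in random lists (percentile 99.9), the highest of the 16 lists. Among these, Flt3 had 4, Wdfy4, Cadm1, Cd24a and Spi1 had 2 each, and Clec9a, Batf3 and Bcl6 were among those with 1. The same list lay at percentiles 99.65 for control and 99.99 for Carm1-KO peaks within 10 kb. The random lists were matched on gene length alone, and whether the excess was particular to anti-HA was not tested. The other lists at or above percentile 99.65 for control peaks within 10 kb lay lower for anti-HA. Their anti-HA percentiles ran from 3.75 (ribosomal proteins) to 87.8 (Toll-like receptor and NF-kB). At gene ends the cDC1 identity list showed no anti-HA excess, with 1 gene against a mean of 0.885 (percentile 59.3). Plasmacytoid dendritic cell markers had an anti-HA interval within 10 kb at 4 of 10 (mean 2.01, percentile 93.9). None of the 25 ribosomal protein genes had one, against a random mean of 2.47 (percentile 3.75).

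Peaks were sparse on the sex chromosomes in all 3 lists. Chromosome X held 26 anti-HA intervals (0.426%, [0.291 to 0.624]), 1134 control peaks (1.92%, [1.81 to 2.03]) and 418 Carm1-KO peaks (1.62%, [1.47 to 1.78]). Per Mb this was 0.155 anti-HA intervals on X, against 1.92 on chromosome 14 and 3.50 on chromosome 11, the autosomes with the lowest and highest density. Control peaks numbered 6.77 per Mb on X and between 18.95 and 29.97 on the autosomes. The Y chromosome held 0 anti-HA intervals, 10 control peaks and 1 Carm1-KO peak.

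**Figure D5:**
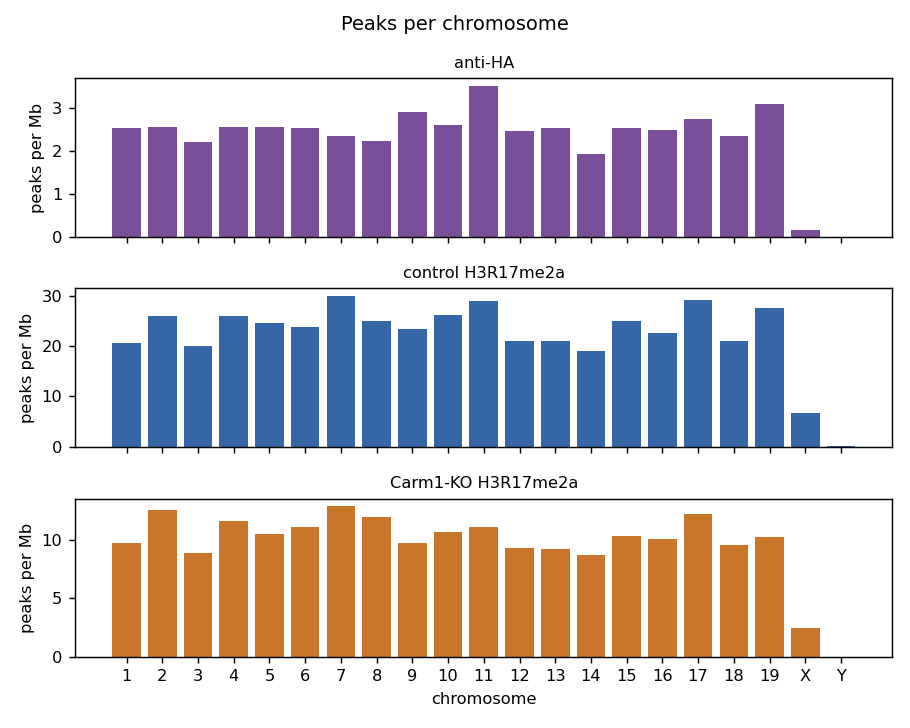
Peaks per Mb (y axes, each from 0) on each chromosome (x axis) in the anti-HA, control H3R17me2a and Carm1-KO H3R17me2a lists. Chromosome X had 0.155, 6.77 and 2.49 peaks per Mb, below every autosome in each list.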

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

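Sequences outside the compared chromosomes were flagged when they held more than 3 anti-HA intervals. The unplaced sequence JH584304 held 26 intervals over 14319 bp, and the mitochondrial genome held 4 intervals over 12722 bp, the widest of 6579 bp. Neither H3R17me2a list had a peak on any sequence outside the compared chromosomes. Whether such sequences were left out before these lists were made is not known, so their absence is not a measured difference from the anti-HA list.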

How the results depend on the processing

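No paired analysis was possible because there was 1 peak list per condition, and leaving out replicates was not run for the same reason. The most upstream start and motif alternatives were not run. The 5 shares that follow are, in order, control peaks without a Carm1-KO peak, Carm1-KO peaks without a control peak, anti-HA intervals on control peaks, anti-HA intervals on Carm1-KO peaks, and control-only peaks with an anti-HA interval, against 72.9%, 34.9%, 19.4%, 7.77% and 1.53% as reported. They were 76.7%, 25.5%, 13.6%, 3.88% and 2.55% at −log10 q of 5 or more, 95.7%, 55.8%, 2.75%, 0.148% and 3.252% at fold 5 or more, 74.2%, 38.03%, 15.4%, 5.65% and 1.14% with overlap of 50% of the shorter interval, and 61.2%, 26.9%, 28.9%, 14.6% and 3.254% with a gap of up to 1000 bp; the cause was not tested. Shared control peaks held an anti-HA interval more often than control-only peaks in each of these alternatives except fold 5 or more, where 9 of 217 shared peaks left the difference within counting error. With the control list shortened, the values other than that of anti-HA on Carm1-KO peaks were 55.6%, 52.3%, 12.8% and 2.39%. Fewer and stronger control peaks were compared there, and the cause of each change was not tested. With control peaks at or above the lowest −log10 p of the Carm1-KO list, chosen after seeing the data, the first and second were 72.4% and 35.7%. Peak counts did not change without merging. Shares at a gene end for anti-HA, control and Carm1-KO were 16.9%, 34.0% and 35.3% within 2500 bp and 3.05%, 11.8% and 13.4% within 250 bp, as the window sets. They were 31.4% and 33.3% for control and Carm1-KO at −log10 q of 5 or more, and 33.0% for the shortened control list, where the cause was not tested. Genes with an anti-HA interval numbered 1219 within 2500 bp and 345 within 250 bp, and genes with a Carm1-KO peak alone 1217 with the shortened control list. Of the 302 list members, 260, 244, 206 and 254 kept their class within 2500 bp, within 250 bp, at −log10 q of 5 or more and with the shortened list, as did 89.7%, 86.5%, 77.5% and 88.2% of all genes. Of 48 list counts, 15, 12, 22, 19 and, with any peak within 10 kb, 25 moved by over 1.5 times. Depth limits weak peaks most, and none is known for anti-HA.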

Other observations

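Gene families, picked by symbol after the lists had been seen, ranged from nearly full to nearly empty of control H3R17me2a peaks at gene ends. A control peak was at 96.2% [89.3 to 98.7] of 78 mitochondrial ribosomal protein genes, 90.2% of 51 proteasome genes and 82.6% of 69 Rab GTPase genes, against 53.3% of all protein-coding genes. It was at 1.26% [0.753 to 2.11] of 1109 olfactory receptor genes, 0.571% of 350 vomeronasal receptor genes and 0.917% of 109 keratin and keratin-associated genes. Of genes with a control peak, 45.2% [44.3 to 46.1] had it in the control list alone. Histone genes stood at 67.2% [54.7 to 77.7] of 61, chemokine genes at 75.0% [50.5 to 89.8] of 16 and interleukin and receptor genes at 30.6% [18.0 to 46.9] of 36. Histone genes are short and repeated, so their calls are uncertain.

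The solved read depth was planned before the data were examined, and its bearing on the peak counts was weighed after its value was seen. The other tests below were chosen after seeing the data. All of the explanations are hypotheses.

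The Carm1-KO list had fewer H3R17me2a peaks than the control list. Lower read depth in Carm1-KO would give a lower solved background there, but per bp of shortest interval (184 and 187 bp) the lowest background was 1.329 times that of the control list, with whole and so unscaled fragment numbers in 100% of the peaks of both. This argues against lower depth under the caller's default background and 1 genome size. A stricter threshold in the Carm1-KO list would bring the counts together, but leaves 57228 control peaks at or above the lowest −log10 p of the Carm1-KO list, against 25826 Carm1-KO peaks. A lower enrichment for a technical reason cannot be told apart from a loss of the mark in Carm1-KO cells: 92.0% of the strongest quintile of Carm1-KO peaks were in the control list, as either may give, and library and genotype are confounded with 1 list each.

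Few anti-HA intervals lay on chromosome X. The share of control peaks on X was 1.92% over the list and 1.08% [0.913 to 1.29] in the strongest quintile, so strength was matched. A shortage of H3R17me2a sites there does not account for all of it: of 1183 control peaks with an anti-HA interval, 3 were on X (0.254%, [0.0863 to 0.743]), against 1.67% from the share on X in 50 bins of −log10 q. A single X in the cells could lower coverage on X and cannot be told apart from other causes: the solved background on X was 0.776 of that on autosomes in the control H3R17me2a list, which says nothing of the anti-HA libraries. No other biological explanation was tested.

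Anti-HA intervals lay more often on control peaks that persisted in the Carm1-KO list. The −log10 q of the control list does not account for all of it. With peaks matched in 50 bins of this value and summit windows of 250 bp on each side, the pooled ratio of shared over control-only peaks was 1.34 [1.176 to 1.52]. The ratio was 1.296 [1.14 to 1.48] with 500 bins. Peak strength itself is not excluded, because a call in the Carm1-KO list is a further measure of strength that the matching does not hold equal. Peak width was not matched either. An explanation by DNA released in any library, such as open chromatin, was not decided. Anti-HA intervals lay on Carm1-KO-only peaks 3.82 times as often as at random places, which CARM1 binding in open chromatin could also give. The ratio was 8.66 for control-only and 12.9 for shared control peaks. The Carm1-HA cells are not the control cDC1, and CARM1 at sites below the caller's threshold was not measured, and no biological explanation was tested.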
